A study of Mus musculus with 2 samples.

How the data were processed

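RNA of E2A-deficient mouse haematopoietic progenitor cells was measured on CodeLink mouse arrays of 1 colour (Cy5 label), per the labels. 1 array held RNA of cells infected with E47ER and 1 array held RNA of cells infected with bHLHER. The design text gives 48 h between infection and induction and 6 h of 4-hydroxytamoxifen. Each group therefore had 1 sample, and no value below has a replicate check.

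The deposited table held an intensity for each of 20289 probes on each array. The values were linear. Their medians were 0.957 for E47ER and 0.953 for bHLHER, which differ by 0.418%. Medians this close to each other point to a common scaling of the deposited intensities, but no source used here states one, and its method and any removal of background are not given in the sources used here. The E47ER array had 119 probes with no value and 45 at or below 0, and the bHLHER array had 125 and 84. Such probes stayed out of all ratios. Because the medians differed by so little, the deposited intensities were used without further normalization, as fixed before the data were examined. The number of arrays, not a read depth, limits the precision. The floor, gene lists, size threshold and rule for named genes were also fixed before the data were examined.

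Probes were named through the platform annotation that accompanies the table. It named 10349 probes, each with 1 gene symbol and none with several, and left 9940 probes unnamed here. All 10349 gene identifiers matched the RefSeq gene table of assembly GRCm38.p6, which was used only for names and older symbols. The named probes covered 10208 symbols, of which 10141 had a value. For a gene with several probes, the probe with the highest mean over both arrays was taken.

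The log2 ratio of E47ER over bHLHER was computed for each gene. The floor was each array's own median over all probes, since no detection call was used here. A gene above the floor on both arrays counted as measured on both sides, and only these genes were ranked and counted. A gene above the floor on 1 array only received a bound, written "at least N-fold", against the higher of the other array's floor and its own value there. A log2 ratio of at least 1 in size, which is a fold of 2, was the threshold for calling a gene higher or lower. This is a threshold of size and not a test, and no p-value was computed because 1 array per group leaves no degrees of freedom.

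For 23 gene lists written beforehand, the median log2 ratio of the members measured on both sides was compared with the medians of 10000 random gene lists of the same size, matched on mean log2 level in 10 bins. A list with a percentile under 2.5 or over 97.5 is called apart from random lists. Such a percentile describes these 2 arrays and is not a test of the conditions. The lists held 721 genes, of which 552 had a named probe with a value, and a list needed 5 measured genes. The mast cell and basophil list had only 4 and was not described further.

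The genes named in the text are the 12 highest and the 12 lowest ratios measured on both sides, the 5 largest bounds in each direction, up to 4 members of each list past the size threshold, and 22 genes chosen whatever their values. Of these 22, Tcf3, Id1, Igll1 and Notch1 had no named probe and are not analysed here. Further genes are named where they illustrate a list, and these were chosen after their values were seen.

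The only measured spread came from genes with 2 probes above the floor on both arrays. It holds probe and array noise and not the variation between cultures.

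Alternatives were quantile normalization, loess of the ratio on brightness (limma), scaling to the 75th percentile, floors at the 25th and 75th percentiles and no floor, the mean over a gene's probes, a pseudocount equal to each array's 25th percentile, a size threshold of 1.5 on the log2 scale, lists without shared genes and 20 bins for the random lists. Centring on the median of pan-leukocyte genes, and 8 further gene lists, were added after seeing the data, as were repeats of the comparison with pan-leukocyte genes at each floor and in 2 parts split at the 75th percentile by a gene's mean level.

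The procedure was tested on simulated data made from the real levels of E47ER against bHLHER. Of 200 genes changed 2-fold, 102 (51%) were recovered among 5563 genes measured on both sides. At 3-fold 162 of 200 (81%) were recovered, and at 4-fold again 162 of 200 (81%), so larger changes were missed too. A changed gene that fell below the floor on either array could not be recovered. In the runs at 2-, 3- and 4-fold, 10, 12 and 12 further calls were of unchanged genes or of the wrong direction. Of 200 simulated lists of 18 genes with no shift, 11 (5.5%) were called apart from random lists, and all 200 lists with a shift of 0.5 were. A true 2-fold change lies on the threshold itself, so noise decides on which side it falls. The unshifted lists were drawn at random like the reference lists, so a share near 5.5% follows by construction. Simulated noise was independent between probes and scaled to these 2 arrays. These rates therefore do not cover co-regulated genes or variation between cultures.

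Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.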

Results

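Gene expression was compared between E2A-deficient mouse haematopoietic progenitors that carried E47ER and those that carried bHLHER, both given 4-hydroxytamoxifen for 6 h. E47 is a transcription factor encoded by the E2A gene (Tcf3), which these cells lack. In fusions to the hormone-binding part of the oestrogen receptor, the protein is held inactive until 4-hydroxytamoxifen binds. The comparison addresses which genes differ between induced E47ER and induced bHLHER, the other arm. No uninfected or untreated array was present. A gene higher with E47ER may therefore have risen in that arm or fallen in the bHLHER arm. Each arm was measured on 1 array, so the differences have no replicate check and carry no p-value. On the 20036 probes with values above 0 on both arrays, log2 intensities had a Pearson r of 0.973 and a Spearman rho of 0.979 across probes, which are not independent replicates.

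Most genes differed little between the arrays, and the larger differences were mostly toward a higher level with E47ER. Of 5534 genes measured on both sides, 128 were at least 2-fold higher in E47ER and 45 at least 2-fold lower, while 5361 lay between. A further 35 genes were above the floor with E47ER only and at least 2-fold higher by their bound, against 5 genes with bHLHER only. Among the 4206 unnamed probes measured on both sides, 73 were at least 2-fold higher and 27 at least 2-fold lower. The middle 95% of genes ran from -0.79 to 0.96 on the log2 scale, and the median of all measured genes was -0.05. The split of higher and lower genes depended on centring: it was 83 and 189 once log2 ratios were centred on pan-leukocyte genes, a choice made after seeing the data that lowers every log2 ratio by the same 0.29. Beside every gene group described here, stromal and fibroblast markers were lower on the E47ER array, with a median log2 ratio of -0.54, and pan-leukocyte genes were higher, with a median of 0.29. In 34 genes with 2 measured probes, the ratios of the 2 probes differed by a median of 0.236, and the SD of the difference was 0.752 on the log2 scale. Without the widest pair, Sapcd1, this SD was 0.371.

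The Id2 gene, whose product binds E proteins and keeps them from DNA, was 12.5-fold higher with E47ER, at an intensity of 95.9 against 7.65. Irf8, a transcription factor of dendritic cell, monocyte and B cell development, was 7.55-fold higher (16.4 against 2.17). Pdgfa, a growth factor subunit, was 8.23-fold higher, and Kmo, an enzyme of tryptophan breakdown, 5.93-fold higher. Lztfl1 reached an intensity of 50.6 with E47ER and was 5.73-fold higher, and Serpinb9g was 6.34-fold higher. Stom, which encodes the membrane protein stomatin, the calcium pump gene Atp2a1, Fstl3, the scavenger receptor gene Marco and Lat, an adaptor of T cell receptor signalling, were 7.58-, 7.25-, 5.47-, 4.86- and 4.95-fold higher. These 5 genes lay between 0.977 and 1.14 on the bHLHER array, just above its floor of 0.953, so their folds depend on dim values. The highest ratio among genes measured on both sides, 12.7-fold for Sapcd1, rested on 1 of its 2 probes, since the other had a log2 ratio of -0.16.

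The largest bounds among genes above the floor with E47ER only belonged to Ly6d, Cd7, Gpr20, Tbc1d8 and Serpinb9. Ly6d, a marker of early B lineage progenitors, was at least 16.3-fold higher, with an intensity of 15.5 against 0.188. Cd7, a surface protein of early T and natural killer cells, was at least 10.8-fold higher. Gpr20 was at least 6.21-fold, Tbc1d8 at least 5.69-fold and Serpinb9, a granzyme B inhibitor, at least 5.05-fold higher.

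The lowest ratios were smaller in size. Col19a1, a collagen gene, was 5.31-fold lower with E47ER (1.84 against 9.77). Clec4e, a C-type lectin receptor of myeloid cells, was 4.05-fold lower, and the chemokine gene Ccl3 was 3.88-fold lower. The neutrophil collagenase gene Mmp8 was 2.73-fold lower, and Ndrg1 3.40-fold lower. Clec4e and Ndrg1, at 1.21 and 1.11 on the E47ER array, lay just above its floor of 0.957, so these folds depend on dim values too. Among brighter genes, Emb was 2.67-fold lower at 44.9 against 119.9, Stap1 2.85-fold lower and Ctr9 2.98-fold lower. Il18rap, which encodes a subunit of the interleukin-18 receptor, was 2.62-fold lower, and Il18r1, the other subunit, 2.12-fold lower. Anxa3, Vwa1 and Elk3 were 2.71-, 2.68- and 2.62-fold lower. Of genes above the floor with bHLHER only, Clec4d was at least 3.70-fold lower with E47ER, Rasgef1b at least 2.51-fold, Calcrl at least 2.43-fold, Gfi1b, a repressor of erythroid and megakaryocytic cells, at least 2.28-fold and Stab1 at least 2.07-fold.

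**Figure D1:**
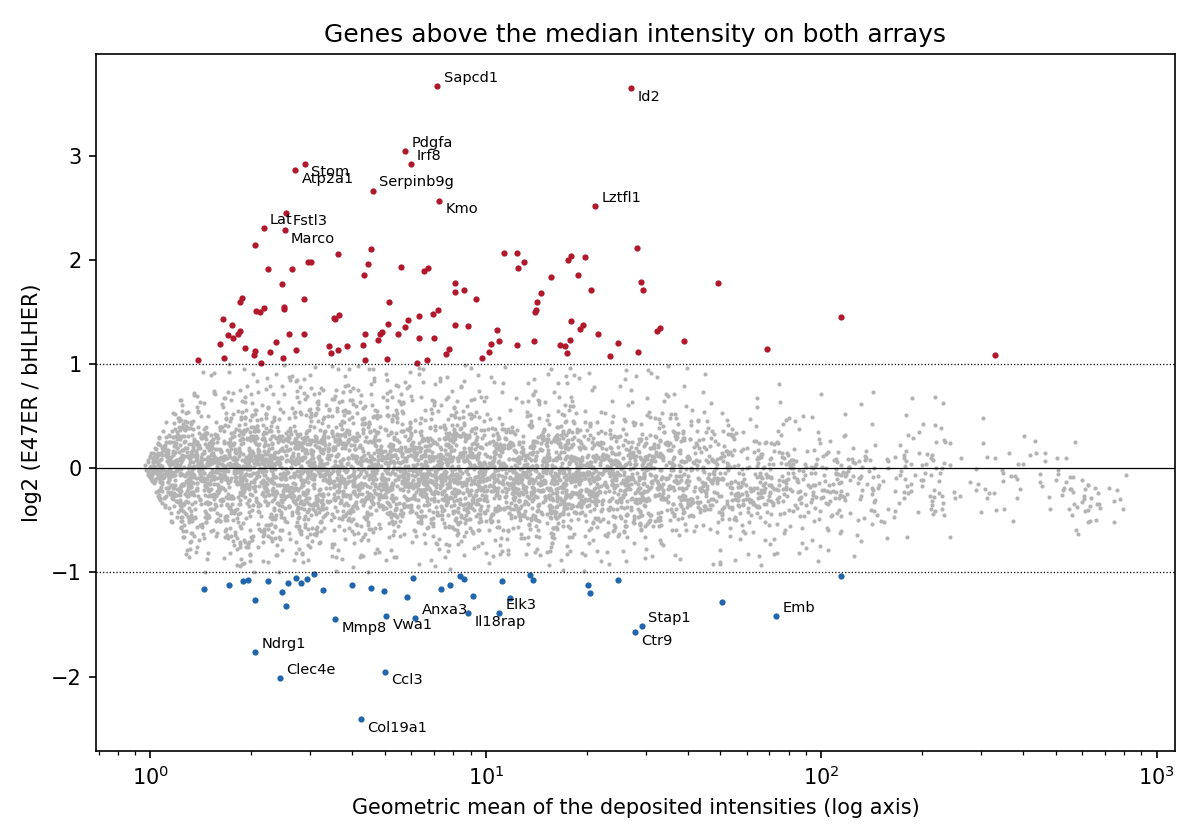
Each point is a gene above the floor on both arrays (5534 genes), with the geometric mean of its 2 deposited intensities on a log axis and the log2 ratio of E47ER over bHLHER on the other axis. Red points are the 128 genes at least 2-fold higher, blue points the 45 genes at least 2-fold lower, dotted lines mark log2 ratios of 1 and -1, and the 12 highest and 12 lowest genes are named.

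Genes tied to E2A activity in lymphocytes were higher as a group with E47ER. Of 27 list members on the array, 9 were measured on both sides, of which 4 were at least 2-fold higher, 1 at least 2-fold lower and 4 between. Besides Id2 and Irf8, Il7r, the interleukin-7 receptor chain needed by lymphoid progenitors, was 4.18-fold higher (25.2 against 6.05), and Cdkn1a, the cell cycle inhibitor p21, was 2.32-fold higher (59.5 against 25.6). Rag2, a subunit of the recombinase of antigen receptor genes, was 2.09-fold lower. The list's median log2 ratio was 0.84, at percentile 100 of matched random lists, whose central 95% ran from -0.31 to 0.23. The size of this median depended on the floor, with 0.45 at the 25th percentile, 1.22 at the 75th and 0.31 with no floor, and it was 0.55 with the centring, where Cdkn1a, at 0.93, no longer passed the threshold and 3 members did. A further 6 members were above the floor with E47ER only, but only 1 of them was at least 2-fold higher by its bound. This was Ptcra, the pre-T cell receptor alpha chain, at least 2.15-fold higher. Gata3, a T lineage factor, was at least 1.56-fold higher, and Rag1, at 1.02 against 0.921, lay next to the floor. Gfi1b and Gfi1 were above it with bHLHER only. Gfi1b was at least 2.28-fold lower with E47ER, while Gfi1, at 0.953 with bHLHER, lay at the floor. All 9 measured members are also in other lists, so this list could not be described without shared genes and is not independent of them.

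Among the other genes chosen in advance, Id3 was 1.79-fold higher, below the size threshold. The remaining E protein genes Tcf4 and Tcf12 had log2 ratios of -0.57 and 0.08, and Socs1 had -0.28. Ebf1 and Pax5, factors of B lineage commitment, were below the floor on both arrays, as were Notch3, Hes1 and Socs3, and no fold is given for them. Rag1 had an intensity of 1.02 with E47ER and 0.921 with bHLHER, next to the floor. Esr1, the oestrogen receptor gene from which such fusions take their hormone-binding part, had an intensity of 3.86 with E47ER and 0.0726 with bHLHER, at least 4.05-fold higher. By their names both constructs carry a part of that receptor, and whether this probe reads it is not given in the sources used here, so these values do not show whether either construct was expressed.

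**Figure D2:**
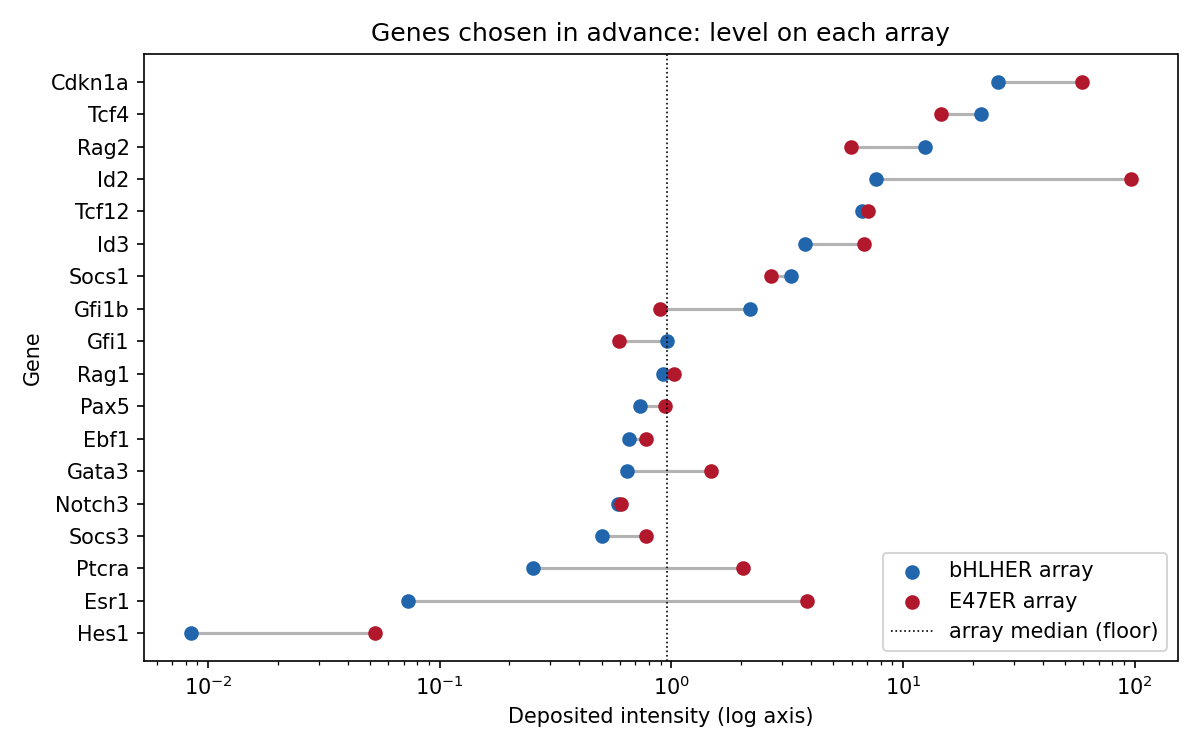
Deposited intensity on a log axis for the 18 genes chosen in advance that have a named probe, with the bHLHER array in blue and the E47ER array in red, 1 array each. The dotted line is the E47ER array median used as its floor (0.957); Id2 was at 7.65 with bHLHER and 95.9 with E47ER, while Ebf1, Pax5, Notch3, Hes1 and Socs3 lay below the floor on both arrays.

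Of the 22 lists described, 7 were above and 1 was below matched random lists, where 1.1 would lie outside by chance if genes varied independently. Genes of a list that vary together would raise that number, so it is no measure of chance for these lists. The interferon response list had the most members past the threshold on the higher side. Of its 18 members measured on both sides, 5 were at least 2-fold higher, none at least 2-fold lower and 14 above 0, with a median log2 ratio of 0.79 at percentile 100. The median was 0.25 at percentile 99.5 over the 9 members left with a floor at the 75th percentile, and 0.51 with the centring, where 3 members passed the threshold and Gbp3 (0.87) and Irf1 (0.77) did not. Irf7, a factor of interferon induction, was 3.90-fold higher (8.80 against 2.26), H2-T23, a non-classical class I gene, 2.86-fold, Isg20 2.83-fold and Gbp3 2.23-fold higher, and the other was Irf1, 2.08-fold higher. Isg20 and Gbp3 were at 1.26 and 1.28 on the bHLHER array, near its floor of 0.953, so their folds depend on dim values. Usp18 was above the floor with E47ER only. 13 members were above the floor on neither array or lacked a value, among them Isg15 (0.487 against 0.478), and B2m, at 199.8 against 262, had a log2 ratio of -0.39.

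Dendritic cell and antigen presentation genes were higher at the median, with 3 of 15 measured members at least 2-fold higher, none lower and 12 between. Irf8 and Irf7 were 2 of these, and the integrin gene Itgax (CD11c) was the other, 3.70-fold higher. Cst3 (121 against 120.5) and Xcr1 (11.1 against 11.2) were nearly level. The median log2 ratio was 0.33, at percentile 99.97, and 0.04 with the centring on pan-leukocyte genes. Cytokine receptor and signalling genes had 4 members at least 2-fold higher, 2 lower and 22 between, with a median of 0.30 at percentile 100 that was 0.0076 with the centring, where Tnfrsf9 (0.92) and Jak2 (0.77) no longer passed the threshold and 2 members were higher and 3 lower. Il7r led the higher members, with Ltb, which encodes lymphotoxin beta, 3.22-fold and Tnfrsf9 2.31-fold higher, and Jak2 2.08-fold higher (2.39 against 1.15, the latter near the floor), while Tnf was 2.28-fold lower and Il18r1 was the other lower member.

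Cholesterol and lipid synthesis genes were mostly higher by small amounts. None of 16 measured members passed 2-fold, 15 lay above 0, and the median log2 ratio was 0.36 at percentile 99.97, and 0.07 with the centring. Nsdhl (14.9 against 8.46) and Idi1 (16.0 against 10.3), enzymes of the sterol pathway, had log2 ratios of 0.82 and 0.63. Cell cycle genes had a median of 0.19 at percentile 100, with 28 of 36 members above 0 and 1 at least 2-fold higher, but the median turned to -0.10 with centring on pan-leukocyte genes. The gene past the threshold was Ccnd3, cyclin D3, 3.81-fold higher. Mcm6 and Ccnb2 had log2 ratios of 0.60 and 0.63, and Pcna 0.01. The apoptosis and survival list had a median of 0.14 at percentile 97.9, which turned to -0.09 at percentile 45.3 with a floor at the 75th percentile and to -0.14 with the same centring, and was 0.32 with no floor and 0.22 after loess. Its 2 members past the threshold were Bcl2a1b, 3.42-fold higher, and Traf1, 2.91-fold higher (3.71 against 1.27, the latter near the floor). None of 19 was at least 2-fold lower, against 2 with the centring. Bcl2a1b has near-identical copies in the mouse genome, so its probe may read several.

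Stromal and fibroblast genes formed the only list below random lists. Of 19 measured members 3 were at least 2-fold lower with E47ER, none at least 2-fold higher and 17 below 0, with a median log2 ratio of -0.54 at percentile 0, and -0.83 with the centring, where 7 were at least 2-fold lower. The matrix genes Bgn and Col6a1 were 2.23- and 2.22-fold lower, and Timp3, an inhibitor of metalloproteinases, was 2.12-fold lower, but lay below the threshold with the pseudocount (-0.96). Acta2 (12.3 against 22.8) and Sparc (10.9 against 18.6) had log2 ratios of -0.88 and -0.78. Igfbp4 went the other way, with a log2 ratio of 0.73. With a floor at the 75th percentile too few members remained to describe this list.

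**Figure D3:**
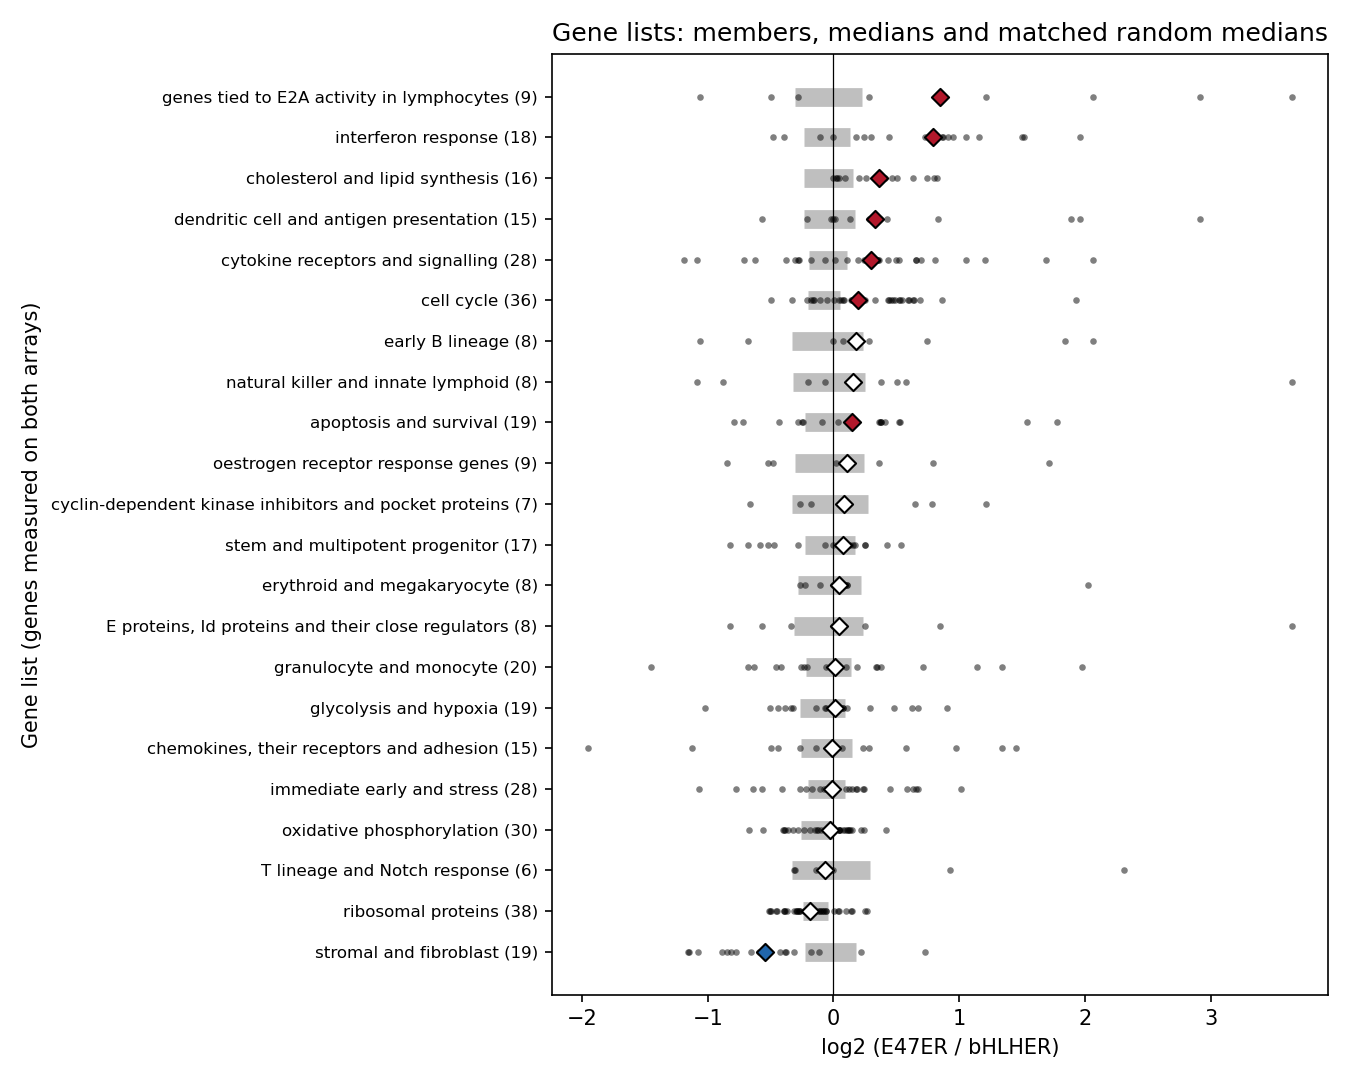
Log2 ratios of E47ER over bHLHER for the members of 22 gene lists measured on both arrays (black points, their number in brackets), with the list median (diamond) and the central 95% of medians of 10000 matched random lists (grey bar). Red diamonds are the 7 lists above random lists, the blue diamond is the stromal and fibroblast list at -0.54, and white diamonds lie inside the range.

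The lineage lists other than the dendritic list lay inside the range of random lists, with single members past the threshold. Of the 14 lists inside the range, 12 had a median that changed sign or went to 0 under at least 1 alternative setting other than the centring. In the early B lineage list, 2 of 8 measured members were at least 2-fold higher, Il7r and the kinase gene Syk (3.58-fold), 1 was lower, Rag2, and 5 lay between. Its median was 0.18 at percentile 94.8 and went above random lists, at percentile 99.7, with a floor at the 25th percentile. Ly6d of this list, above the floor with E47ER only, was at least 16.3-fold higher, and no member was at least 2-fold lower by its bound. In the T lineage and Notch response list only 6 of 26 members were measured on both sides, and Lat was the 1 past the threshold. Its median was -0.07 and its mean 0.41, and with a floor at the 25th percentile the median turned to 0.23 and went above random lists, at percentile 98.7. Cd7 and Ptcra of this list, above the floor with E47ER only, were at least 10.8- and 2.15-fold higher, and no member was at least 2-fold lower by its bound. In the granulocyte and monocyte list, 3 of 20 members were higher, 1 was lower and 16 lay between. Fcgr2b, an inhibitory antibody receptor, was 3.94-fold, the integrin gene Itgb2 2.53-fold and the adaptor gene Tyrobp 2.20-fold higher (log2 0.85 with the centring, below the threshold), and Mmp8 was the lower one. Tfrc, the transferrin receptor, was 4.06-fold higher and the 1 member of 8 in the erythroid and megakaryocyte list past the threshold. Gfi1b of this list, above the floor with bHLHER only, was at least 2.28-fold lower with E47ER. No member was at least 2-fold higher by its bound. In the natural killer and innate lymphoid list, of 8 measured members, Id2 was the higher and Il18r1 the lower member past the threshold. None of 17 measured stem and multipotent progenitor genes passed it; Lmo2 had a log2 ratio of -0.82 and Hoxa9 -0.52.

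The remaining lists also lay inside the range. Of 15 chemokine, receptor and adhesion genes, Selplg, the selectin ligand PSGL-1, was 2.73-fold higher at 189 against 69.1, Itgb2 was higher, and Ccl3 and Ccr2 (2.18-fold) were lower. Of 28 immediate early and stress genes, Sgk1 was 2.02-fold higher and Myc 2.10-fold lower (9.54 against 20.1), and 26 lay between. Sgk1 lost its place past the threshold with 75th percentile scaling (0.998), the pseudocount (0.93) and the centring (0.72). Cdkn1a was the 1 member of 7 past the threshold among cyclin-dependent kinase inhibitors and pocket proteins, Id2 the 1 of 8 among E and Id proteins and their regulators, Xbp1 (3.28-fold higher) the 1 of 9 among oestrogen receptor response genes, and Pfkm (2.03-fold lower) the 1 of 19 among glycolysis and hypoxia genes. Pfkm was below the threshold after loess (-0.96) and quantile normalization (-0.99). None of 38 ribosomal protein genes and none of 30 oxidative phosphorylation genes passed it, with medians of -0.19 and -0.03. The median and mean differed in sign for chemokines, receptors and adhesion (-0.01 and 0.03), immediate early and stress genes (-0.01 and 0.03), stem and multipotent progenitor genes (0.08 and -0.08) and glycolysis and hypoxia genes (0.01 and -0.00074).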

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

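No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. The counts of 128 higher and 45 lower genes moved with the floor: 204 and 77 at the 25th percentile, 43 and 16 at the 75th, and 545 and 348 with no floor, where dim probes enter. A size threshold of 1.5 gave 56 and 6, and centring on pan-leukocyte genes, added after seeing the data, gave 83 and 189. Quantile normalization, loess, 75th percentile scaling, the mean over probes and the pseudocount kept both counts within 1.5 times. That centring moved the median of all genes from -0.05 to -0.34, and no other scaling moved it by over 0.1 on the log2 scale. Of 231 list medians under the alternatives, 225 stayed on the same side of the random range and 35 changed sign or went to 0, of which 32 were of the 14 lists inside the range and 11 came with the centring. The centring and the 75th percentile scaling move every log2 ratio alike, so their percentiles could not change. Their part of the 225 was therefore fixed in advance. Without shared genes, the lists of E2A-tied genes, E and Id proteins, early B lineage and natural killer cells had too few members left. Changes of side, and of sign in lists apart from random, follow, and their cause was not tested. Apoptosis and survival turned to -0.089 with the floor at the 75th percentile and to -0.14 with the centring, and cell cycle to -0.10 with the centring, which moves every gene alike and so cannot change a percentile. With it the added pan-leukocyte list went to 0 by construction, and the unfolded protein response and secretory pathway list turned to -0.16. With the floor at the 25th percentile, T lineage and Notch response (0.23) and early B lineage (0.24) went above random lists, as did early B lineage (0.24) and natural killer and innate lymphoid (0.27) with no floor, and oxidative phosphorylation (0.0068) with the floor at the 75th percentile. At that floor 0 lists lay below random lists, because the stromal list had too few members left. The dendritic list had too few members there as well. The SD between probes of a gene fell to 0.230 at that floor, where the widest pair, Sapcd1, was no longer measured. At the main floor it was 0.371 without that pair. Of 475 values of 57 named genes, 465 stayed on the same side of the size threshold, 10 fell below it (Cdkn1a, Gbp3, Tnfrsf9 and Tyrobp with the centring, Pfkm after loess and quantile normalization, Timp3 with the pseudocount, Sgk1 with the pseudocount, 75th percentile scaling and the centring) and 1 changed sign, Tcf12 (-0.20 with the centring); 38 more could not be had because the gene was not above the floor there. A change of floor cannot alter a gene's ratio, and the mean over probes can alter only genes with several probes. Much of the agreement among these 475 values was therefore fixed in advance. Signal over background limits dim genes. Those above the floor on 1 array only have a bound, and those below it on both have no fold. Folds of genes just above the floor are given but depend on dim values.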

Other observations

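The 8 added gene lists and the tests that use them were chosen after the main results had been seen, and the values of some members, such as Ptprc and Btk, were known by then. The tests of the leukocyte share at other floors and split by level were added after its first result was seen. Genes of the nucleolus and ribosome biogenesis were lower with E47ER, as Myc was. None of 33 measured members passed 2-fold, but 30 lay below 0, and the median log2 ratio was -0.30 at percentile 0.03 of matched random lists, and -0.59 with centring on pan-leukocyte genes. Gnl3, Grwd1 and Wdr12 had log2 ratios of -0.92, -0.83 and -0.74, and the abundant Ncl and Npm1 had -0.42 and -0.20. Genes of the unfolded protein response and secretory pathway, listed because Xbp1 was higher but without it, had a median of 0.13 at percentile 99.7, with Herpud1 at 0.83, Dnajc3 at 0.82 and Hspa5 at 0.18; this median turned to -0.16 with centring on pan-leukocyte genes. Pan-leukocyte genes themselves had a median of 0.29 at percentile 100, with Cd52, Stk17b, Dok3 and Laptm5 at least 2-fold higher among 30, while Cd53 had -0.56 and Stk10 -0.29.

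Lysosomal genes, listed because Grn, Psap and Ppt1 were at least 2-fold higher but without those 3, had a median of 0.03 at percentile 87.7, with Ctsl the 1 of 37 past 2-fold. Genes of p53 response, listed beside Cdkn1a and holding it, had a median of 0.01 and a mean of -0.0024 at percentile 64.5, although this went to 0.41 at percentile 99.3 with the floor at the 75th percentile. Inflammatory myeloid genes, listed beside Clec4e and Ccl3 but without them, had a median of -0.01 and a mean of 0.03 at percentile 55.4, and proteasome genes -0.14 at percentile 45.7.

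The lower level of stromal and fibroblast genes with E47ER, at a median of -0.54, was weighed against fewer stromal cells in that culture and against a trend with brightness. A trend with brightness is argued against, because the list lay at percentile 0 of random lists matched on level, which carry such a trend too. After loess the median was -0.53 at percentile 0. That matching left this repeat little room to come out otherwise, so it adds little. Fewer stromal cells is a candidate explanation: a second list of mesenchymal genes that shares no member with the first had a median of -0.47 at percentile 0, with 14 of 14 measured members below 0, and neither list shares a gene on the array with any other list, with Acta2 at 22.8 and Sparc at 18.6 in the bHLHER culture. A lowering of these genes by E47 within the cells, or a rise by bHLHER, remains open and untested. With 1 array per group neither can be separated from fewer stromal cells, and no label says whether the cells were grown with stroma or sorted.

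The higher level of interferon response genes, at a median of 0.79, was weighed in the same way. A trend with brightness is argued against by percentile 100 among random lists matched on level. The repeat after loess, with a median of 0.81 at percentile 100, adds little because of that matching. A larger share of leukocytes in the E47ER culture is argued against as the cause of the whole shift: the list lay 0.51 above the pan-leukocyte median, at percentile 99.98 of such differences between random lists, 0.55 above with the floor at the 25th percentile and 0.43 with no floor. Split by mean level, its 8 dimmer members, some near the floor, lay 0.70 above (percentile 99.94), but for the 10 brighter ones such a share stays open, at -0.0094 (percentile 47.8), as for the 9 left with the floor at the 75th percentile, at -0.0022 (percentile 51.2). An effect of E47, an effect of bHLHER and a difference between the cultures, such as in infection, also remain open, because each group is 1 culture.

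For cell cycle genes, at a median of 0.19, brightness is argued against by percentile 100 among random lists matched on level. The repeat after loess, with a median of 0.28 at percentile 99.99, again adds little. A larger share of leukocytes stays open: the list lay 0.10 below the pan-leukocyte median (-0.10, percentile 21.5). The percentile lay inside the random range at the other floors too. Only a list well above the pan-leukocyte median could have failed this comparison, so it gives such a share no support. Raising leukocyte genes by their median through a larger share of leukocytes needs other cells to give RNA in the bHLHER culture. They would give at least 18.1% of it if none were left in the other culture. They would give 41.3% if their genes were lower only by the stromal median. Of 29 stromal genes on the array, 19 lay above the floor on both arrays, at a median of -0.54. The floor is not a detection call, and this median covers only genes that passed it with E47ER. These values therefore do not decide the case of none left. In the bHLHER culture the brightest gene of the 2 mesenchymal lists, Acta2, was at 22.8, against 399.8 for Actb. Intensities of single genes do not measure a share of RNA, so the 41.3% was not tested. A change of the cell cycle by E47 or by bHLHER remains open.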
